A study of Mus musculus with 12 samples.

How the data were processed

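RNA sequencing of O4-positive mouse cells was examined from the processed table of the series, in 7 Control and 5 Chd7iKO libraries. Per the labels' protocols, cells of cortex and corpus callosum were sorted with magnetic beads at postnatal day 7, and RNA was made into libraries with a stranded mRNA kit. Pups of both groups received tamoxifen (20 mg/ml) under the skin, 40 µl at postnatal day 1 and 30 µl at postnatal day 4. Groups were taken from the sample titles and the genotype labels. The submitters' processing notes name TopHat2, Bowtie, featureCounts, edgeR and the mouse genome build mm10, with no role, order or version, and the gene annotation is not given in the sources used here.

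The authors deposited estimated counts per gene, not scaled, for 14107 genes in each of the 12 libraries. Of all values, 1.76% (2973) were not whole numbers, so that reads may have been shared between genes, and genes with near-identical copies, such as protocadherin clusters and ribosomal proteins, are uncertain to that extent. All 12 columns matched a sample by name. The lowest mean over the libraries was 20.8 counts for any gene, so that the table starts above the counts of weakly expressed genes, and 12 gene names appear as dates and were kept in the fit but never named. The authors deposited log2 fold changes and p-values of their own comparison in the same table, which were used only to set their number of calls beside the one computed here. The authors also deposited other lists with no numeric values, of genes bound by Chd7, bound by Chd7 and Chd8, regulated and bound, or linked to autism risk; the rule that tied binding sites to genes is not given in the sources used here. A sheet of gene ontology terms was not used here.

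Estimated counts were rounded to whole numbers. Total estimated counts were 30384507 to 35512310 per library, and the biological coefficient of variation was 14.7%. CPM, counts scaled to a common library total, were computed here after TMM scaling, and mean levels of gene lists are means of log2 CPM with a prior count of 2. Within each group, 31 pairs of libraries were compared over genes with at least 10 counts; the lowest chi-square per degree of freedom was 9.14 and the correlations of log2 CPM were 0.978 to 0.994, so that no pair agreed within sampling noise and each library counted as 1 replicate. The first principal component held 45.2% of the variance.

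The main test was edgeR's quasi-likelihood F-test with TMM scaling, edgeR's expression filter (which removed 0 genes) and no covariate, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Standard errors and intervals come from the same fit. The targeted gene was also tested with an exact permutation test over all 792 splits of the libraries into 7 and 5. Gene lists were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, with adjustment over the 21 lists that had measured members. Overlaps with the deposited lists were tested with two-sided Fisher's exact tests against all tested genes, and with Mantel-Haenszel odds ratios within 10 bins of mean expression.

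The design, the rule for named genes, the 22 gene lists and most alternatives were chosen before the data were examined. The lists held markers of precursors, committed and newly formed oligodendrocytes and myelin, lineage transcription factors, differentiation inhibitors, p53 targets, apoptosis genes, S phase, G2 and mitosis, cholesterol synthesis, CHD remodellers, the BAF complex, ribosomal proteins, mitochondrial transcripts, immediate early genes, and markers of astrocytes, neurons, microglia, endothelium, mural cells and fibroblasts, ependyma and choroid, and red blood cells. Named genes are Chd7 and Chd8; the 10 largest rises and 10 largest falls among called genes with a mean of at least 1 CPM; up to 4 called members of each gene list and of each deposited list, by smallest adjusted p; and Trp53, Sox10, Olig2, Nkx2-2, Gpr17, Myrf, Pdgfra and Mbp. Predicted genes and pseudogenes were left out, and some genes that the rule selects are not reported here. A list of interferon-stimulated genes, gene families by shared name stem, 7 further deposited sublists, the fits without Controls 3 and 6 or without Chd7iKO 4 and 5, and a covariate of Y-linked genes were added after the data were seen.

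Alternatives covered other scalings (DESeq2 size factors, upper quartile, library totals), DESeq2's Wald test, limma voom with quality weights, other thresholds, the replicate number as a block, a score of other cell types as a covariate, and leaving out each library in turn. The code was tested on simulated data made from these libraries for this comparison, with 14105 genes run and 50 planted at each fold. It recovered 30% of genes planted at 1.25-fold, 66% at 1.5-fold, 88% at 2-fold and 100% at 4-fold, with 4.05% false genes among its calls, and it called the 1 planted list. Simulated genes were drawn independently of each other, so that it does not test calls of lists whose genes are correlated. Chromosome positions are from GENCODE M21, on the same build. Tools were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15 and matplotlib 3.10.9.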

Results

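RNA was sequenced from 12 libraries of O4-positive cells of mouse pups at postnatal day 7. The O4 antibody binds sulfated lipids on the surface of late oligodendrocyte precursors and immature oligodendrocytes, the glial cells that later make myelin. The cells were sorted with magnetic beads from cortex and corpus callosum. According to the labels, both Chd7 alleles were floxed and no Cre was present in the 7 Control libraries, and the 5 libraries labelled Chd7iKO came from littermates that also carried a Cre under the Pdgfra promoter, which is active in oligodendrocyte precursors. Both groups received tamoxifen at postnatal days 1 and 4. Chd7 encodes an ATP-dependent chromatin remodeller, and the comparison asks which transcripts differ after its deletion in the precursor lineage. By these labels no group carried Cre without floxed Chd7, so that the design cannot separate an effect of Cre from one of Chd7 deletion. The table covered 14107 genes, with 30384507 (Chd7iKO 3) to 35512310 (Control 6) estimated counts per library. How many pups made up a library is not given in the sources used here, so that the p-values measure the spread between these samples, which may in part be technical. Xist (462 to 1515 CPM) and 4 Y-linked genes (124 to 197 CPM summed) were found together in Controls 3, 4 and 7 and in all 5 Chd7iKO libraries.

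The Chd7 transcript itself stood at 236 ± 30.9 CPM in Control (SD, n = 7) and 242 ± 28.9 CPM in Chd7iKO libraries (n = 5). This is a log2 fold change of 0.033 (SE 0.098, 95% interval -0.18 to 0.24), and the difference was smaller than the spread between replicates (two-sided exact permutation test over 792 splits, p = 0.760). Single libraries ranged from 179 CPM in Control 3 to 281 CPM in Chd7iKO 1, and the other Chd7iKO libraries had 235, 258, 207 and 227 CPM. Chd7 lies on chromosome 4 from 8690406 to 8867659 (mm10). The values sum reads over the whole gene, while the floxed part is not given in the sources used here, so that they do not check whether the deletion took place. Chd8, a related remodeller, had 164 ± 18.4 and 163 ± 19.8 CPM (log2 fold change -0.012, SE 0.088, edgeR adjusted p = 0.938).

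Across all genes, 2224 were higher and 1943 lower in Chd7iKO cells, together 4167 of 14107 tested (29.5%). Most changes were moderate, with a median absolute log2 fold change of 0.42 among changed genes, and 273 of the higher but 37 of the lower genes differed at least 2-fold. Among the largest rises were Ptprv (log2 fold change 3.35, SE 0.45), the cyclin-dependent kinase inhibitor Cdkn2b (2.66, SE 0.40), the somatostatin receptor Sstr2 (2.60, SE 0.19), the interferon-induced protease Usp18 (2.49, SE 0.36) and the mitochondrial creatine kinase Ckmt1, which rose from 13.9 ± 7.67 to 76.2 ± 8.77 CPM. Hhipl2 (3.13), Clic5 (2.96), the adhesion molecule Madcam1 (2.72) and Mab21l3 (2.46) were in this group too, and each of these genes was higher in 5 of 5 Chd7iKO libraries than in any control. The largest falls were in the dopamine receptor Drd5 (-1.83, SE 0.27), Lad1 (-1.65), Olfm3 (-1.58), the synaptic adhesion protein Slitrk6 (-1.55, SE 0.12), the melanocortin receptor Mc4r (-1.45) and the teneurin Tenm1 (-1.43). The guidance cue Sema3d fell from 242 ± 28.3 to 94.5 ± 4.86 CPM and the matrix protein Edil3 from 190 ± 26.7 to 77.8 ± 6.97 CPM, while the choline transporter Slc5a7 (-1.32) and the guanylate cyclase Gucy2f (-1.26) fell from lower levels.

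Esr1, the gene of estrogen receptor alpha, on chromosome 10 from 4611593 to 5005614, was also among the largest rises (log2 fold change 3.06, SE 1.04, edgeR adjusted p = 0.0401). Its controls did not form one group. Control 3 had 81.7 and Control 6 had 44.7 CPM, the other 5 controls 0.532 to 1.26 CPM, and the Chd7iKO libraries 138 to 171 CPM. The Esr1 call held when Control 1, 3 or 6 was left out and was lost, at adjusted p = 0.0520 to 0.0712, when any of the other 9 libraries was. Without Controls 3 and 6, left out after the data were seen, its log2 fold change was 7.52 (SE 0.15, edgeR adjusted p = 1.03e-10). Controls 3 and 6 had the highest levels among controls in all 10 of the largest rises, with Hhipl2 at 6.06 and 3.29 CPM against 0.554 to 0.841 CPM in the other 5 controls, and without them the log2 fold changes were 4.47 for Hhipl2, 4.33 for Ptprv, 4.12 for Clic5 and 3.56 for Cdkn2b. They were the lowest controls in 1 of the 10 largest falls.

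The count of changed genes came from edgeR's quasi-likelihood test, two-sided, with Benjamini-Hochberg adjustment over all genes, and 5744 genes had an unadjusted p under 0.05. In the authors' deposited table, 3719 genes had an adjusted p under 0.05, and 3485 genes were called in both. Leaving out Chd7iKO 5 alone gave 2690 calls, and leaving out Chd7iKO 4 and 5 together, chosen after the data were seen because they had the highest vascular markers, gave 1747, of which 1719 were among the 4167 with the same direction. Leaving out Controls 3 and 6 gave 4305, of which 3765 were shared. With a score of astrocyte, neuronal, microglial and endothelial markers as a covariate, 1770 genes were called (1701 shared), and limma voom called 6462.

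**Figure D1:**
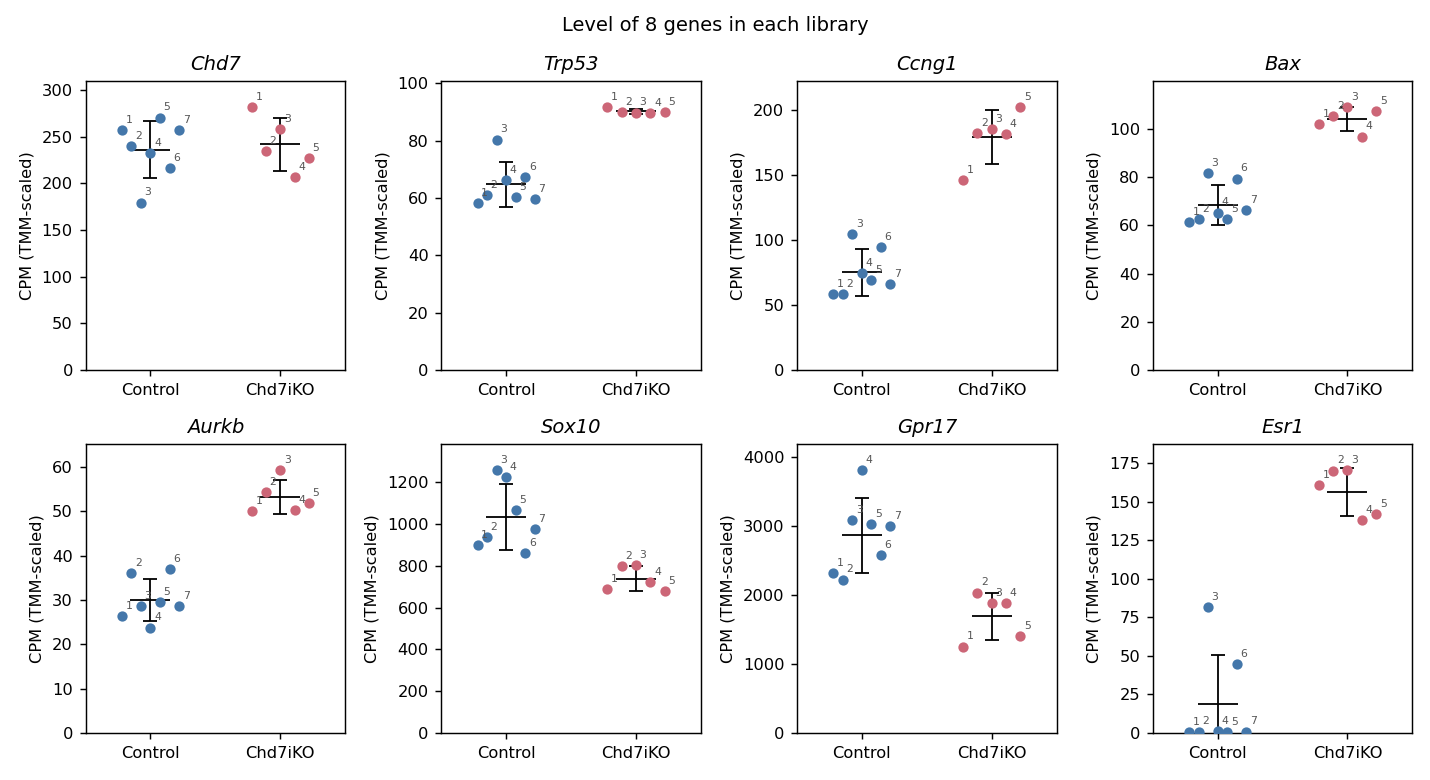
Level of 8 genes in each library, in CPM after TMM scaling (vertical axes, from 0), for the 7 Control and 5 Chd7iKO libraries; points are libraries with their number, horizontal marks are means and bars are SD, drawn no lower than 0. Chd7 overlaps between the groups (236 against 242 CPM on average), Gpr17 is lower in all 5 Chd7iKO libraries, and Controls 3 and 6 stand apart in Esr1 at 81.7 and 44.7 CPM.

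Genes of committed and newly formed oligodendrocytes were mostly lower in Chd7iKO cells. Of the 25 genes in this list, 17 fell and 0 rose in edgeR (1 rose in DESeq2 and 2 in limma voom), with a median log2 fold change of -0.41. Gpr17, a receptor that marks committed precursors, fell from 2868 ± 546 CPM (SD, n = 7) to 1692 ± 343 CPM (n = 5; log2 fold change -0.76, edgeR adjusted p = 0.00254). The sialidase Neu4 fell from 126 ± 14.0 to 70.6 ± 3.62 CPM, and Sema5a (-0.69), Lims2 (-0.69) and Bcas1 (-0.54), a marker of early myelinating cells, also fell. Each of these 5 genes was lower in 5 of 5 Chd7iKO libraries than in any control.

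Among 20 markers of oligodendrocyte precursors, 10 fell and 2 rose, with a median log2 fold change of -0.20. The chondroitin sulfate proteoglycan Vcan fell from 1092 ± 122 to 655 ± 65.4 CPM, C1ql1 from 196 ± 17.4 to 117 ± 14.0 CPM, and Susd5 (-0.98) and Cspg5 (-0.41) also fell. Pdgfra, the receptor that defines these precursors and whose promoter drives the Cre, fell slightly (log2 fold change -0.20, SE 0.065, edgeR adjusted p = 0.0341), a call lost without Control 3, 4, 5 or 7 or Chd7iKO 2, 4 or 5 (adjusted p = 0.0530 to 0.0969) and with scaling to library totals (0.0689). Myelin genes were mixed, with 10 of 32 lower, 3 higher and 19 not past the threshold. Ugt8a, which makes the myelin lipid galactosylceramide, fell from 339 ± 27.8 to 204 ± 18.8 CPM, the plasmolipin gene Pllp by a log2 fold change of -0.62, and Tmem88b by -0.45. Anln rose (0.82, SE 0.12), but it encodes a cytokinesis protein and stands in the mitosis list as well. The myelin basic protein gene Mbp did not pass the threshold, at 2060 ± 345 and 1979 ± 417 CPM (edgeR adjusted p = 0.798).

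Of 19 transcription factors of the lineage, 8 fell and 0 rose. Sox10, required for oligodendrocyte differentiation, lies on chromosome 15 from 79154908 to 79165240 and fell from 1032 ± 158 to 738 ± 59.8 CPM (log2 fold change -0.48, SE 0.10, edgeR adjusted p = 0.00334). Myrf, a factor needed for myelin gene expression, fell from 334 ± 50.4 to 218 ± 27.8 CPM, and Sox8 (-0.63), Zfp488 (-0.41) and Nkx2-2 (-0.41, SE 0.13, adjusted p = 0.0261) fell too, the last with a call lost without Control 4 or Chd7iKO 1, 4 or 5 (adjusted p = 0.0510 to 0.0662). Olig2 stood at 811 ± 111 and 718 ± 61.5 CPM and did not pass (adjusted p = 0.163). Of 22 inhibitors of differentiation, 6 rose and 3 fell; the cell cycle factor E2f1, also in the S phase list, rose (1.08), as did the Notch ligand Jag1 (0.55), while the Notch effector Hey1 (-0.31) and Lingo1 (-0.38) fell.

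Camera, which compares a list with all other genes, called 4 of these lists lower, with adjusted p = 8.57e-08 for committed cells, 5.92e-04 for precursors, 0.00131 for transcription factors and 0.0148 for myelin. None of these calls held with a correlation estimated from the data, at adjusted p = 0.259 with an estimated correlation for committed cells and for precursors, 0.253 for transcription factors and 0.533 for myelin. Adjusted over the list alone, 18 committed genes were lower and 1 higher, 12 precursor genes lower and 2 higher, 10 transcription factors lower and 0 higher, and 10 myelin genes lower and 4 higher. The inhibitors were not called (camera adjusted p = 0.794), with 6 higher and 4 lower adjusted over the list alone. Without Chd7iKO 4 and 5, 3 inhibitors were higher and 1 lower, and Lingo1 lost its call (edgeR adjusted p = 0.0554). Without Controls 3 and 6, 5 inhibitors were higher and 4 lower. The myelin call was lost without Chd7iKO 1 (camera adjusted p = 0.0666). Precursor genes numbered 12 lower without Controls 3 and 6, and 5 lower without Chd7iKO 4 and 5; for committed cells these counts were 17 and 15, for transcription factors 9 and 6, and for myelin 10 and 10. With Controls 3 and 6 left out, the transcription factors were at adjusted p = 0.04998 with an estimated correlation, a call that the fit of all libraries did not give. Those controls were chosen after their values were seen, so that this call is no independent support. Microglial, endothelial and mural markers were higher in the same Chd7iKO libraries, with median log2 fold changes of 0.61, 0.66 and 0.89.

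Targets of p53, the transcription factor that responds to DNA damage and other stress, were higher in Chd7iKO cells. Of 29 measured targets, 23 rose and 1 fell, with a median log2 fold change of 0.81. The death receptor Tnfrsf10b rose from 4.71 ± 1.33 CPM (SD, n = 7) to 15.6 ± 1.78 CPM (n = 5), Ccng1, a cyclin and direct p53 target, from 75.4 ± 17.9 to 180 ± 20.5 CPM, and the nuclease Aen and the DNA polymerase Polk by 2.14-fold and 1.82-fold. The p53 gene Trp53, on chromosome 11 from 69580359 to 69591873, rose from 64.7 ± 7.72 to 90.1 ± 0.816 CPM (log2 fold change 0.48, SE 0.071, edgeR adjusted p = 3.80e-04). The 1 target that fell was Rrm2b, named after its values were seen.

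Of 28 core apoptosis genes, 10 rose and 0 fell. The pore-forming Bax rose from 68.5 ± 8.41 to 104 ± 4.83 CPM, the apoptosome scaffold Apaf1 by a log2 fold change of 0.78, and the BH3-only gene Bbc3 by 0.93. Bax, Bbc3 and Apaf1 are targets of p53 and stand in both lists. All of these named genes, Trp53 included, were higher in 5 of 5 Chd7iKO libraries than in any control.

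Camera called both lists, with adjusted p = 7.16e-12 for p53 targets and 0.00244 for apoptosis genes; for both the adjusted p = 0.253 with an estimated correlation. Adjusted over the list alone, 24 targets were higher and 1 lower, and 10 apoptosis genes were higher and 0 lower. In the mean level of the p53 targets, Controls 3 and 6 lay at 4.82 and 4.61 log2 CPM, the other 5 controls at 4.05 to 4.38 and the Chd7iKO libraries at 5.24 to 5.39. When Controls 3 and 6 were left out, 23 targets were higher and 0 lower, and 11 apoptosis genes were higher. Camera with an estimated correlation then gave adjusted p = 0.0372 for the targets and 0.0398 for apoptosis genes. Those controls were chosen after their values were seen and had the highest p53 target means among controls. Leaving them out favours such calls, so that these are no independent support. Without Chd7iKO 4 and 5, 22 targets and 8 apoptosis genes were higher. Microglial markers (median log2 fold change 0.61) and immediate early genes (0.50) were higher in the same libraries.

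**Figure D2:**
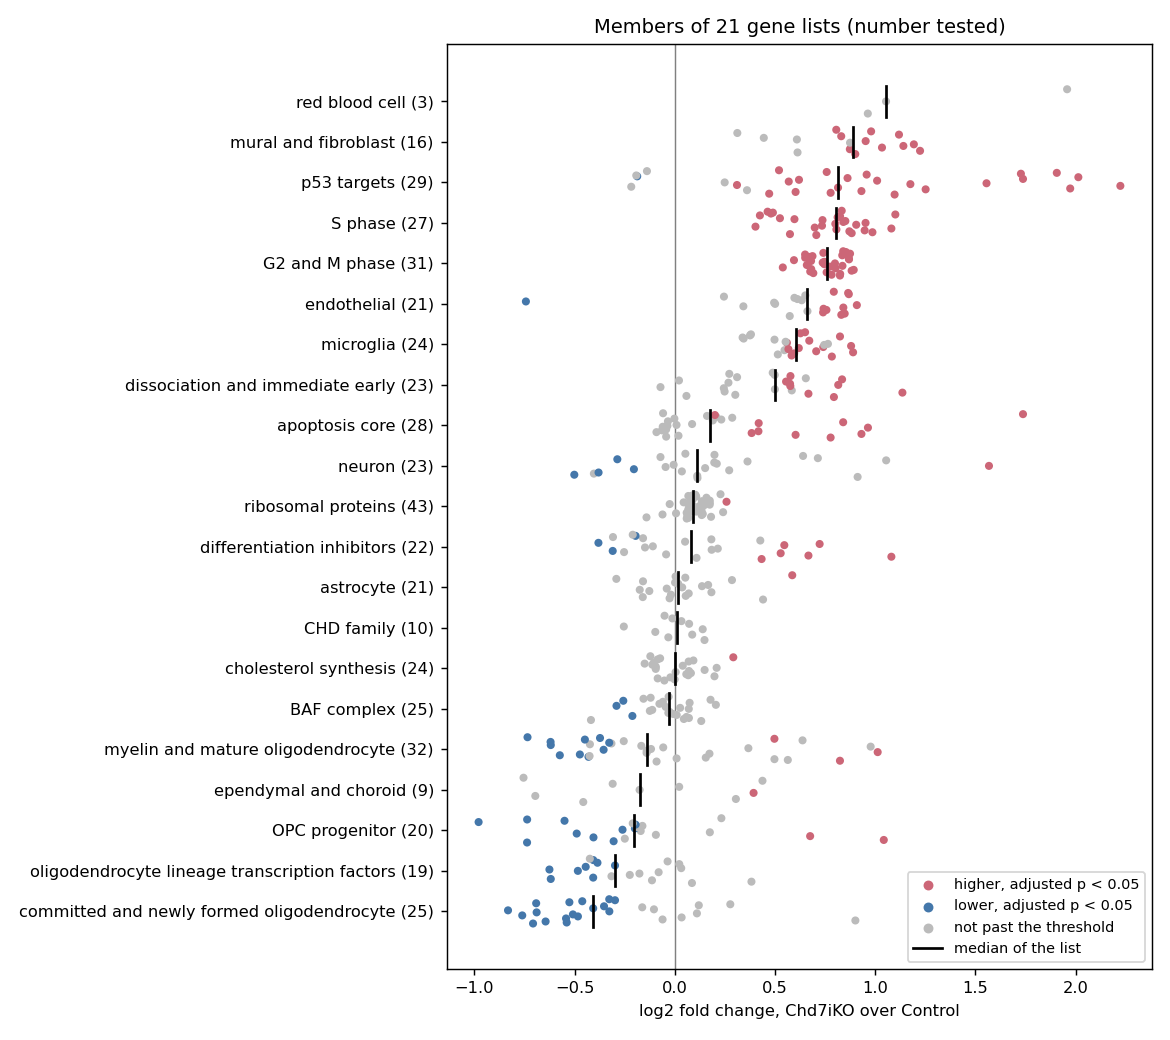
Log2 fold change of Chd7iKO over Control (horizontal axis) for every measured member of 21 gene lists (vertical axis, with the number tested); red points are higher and blue points lower at an edgeR adjusted p under 0.05, grey points did not pass, and black lines are medians. All 31 mitosis and all 27 S phase genes lie to the right of 0, and the committed oligodendrocyte list has its median at -0.41.

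Cell cycle genes rose together. All 27 S phase genes and all 31 genes of G2 and mitosis passed the threshold, with median log2 fold changes of 0.81 and 0.76. The mitotic kinase Aurkb rose from 30.0 ± 4.85 CPM (SD, n = 7) to 53.2 ± 3.84 CPM (n = 5), Plk1 from 30.5 ± 4.73 to 54.5 ± 4.87 CPM, and the anaphase activator Cdc20 and the kinesin Kif23 by log2 fold changes of 0.80 and 0.87. In S phase, the replicative helicase subunit Mcm4 rose from 65.2 ± 16.1 to 117 ± 16.1 CPM, the epigenetic maintenance factor Uhrf1 by 0.83 and thymidylate synthase, Tyms, by 0.46 on the log2 scale.

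Camera gave adjusted p = 7.16e-12 for S phase and 1.51e-17 for G2 and mitosis. These calls were lost at adjusted p = 0.404 with an estimated correlation for S phase and 0.259 for mitosis. Adjusted over the list alone, all 27 and all 31 genes were again higher. Control 6 had the highest S phase mean among the controls (5.35 log2 CPM), above Chd7iKO 1 (5.19) and below the other Chd7iKO libraries (5.58 to 5.73). Without Controls 3 and 6 the counts were 27 and 31, and without Chd7iKO 4 and 5 they were 14 and 29. Median log2 fold changes in the same libraries were 0.61 for microglial, 0.66 for endothelial and 0.89 for mural markers.

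Markers of other cell types moved as well, although the cells had been sorted for O4. Of 24 microglial genes, 14 rose and 0 fell, among them Cd68, a lysosomal protein of phagocytes (16.9 ± 4.51 to 27.6 ± 2.11 CPM), the Fc receptor subunit Fcer1g (log2 fold change 0.88), Laptm5 (0.67) and Cd14 (0.89). Of 21 endothelial genes, 10 rose, with the tight junction gene Cldn5 at 50.4 ± 13.2 and 90.7 ± 32.1 CPM, Sox17 at 0.87 and Esam at 0.74. The 1 endothelial gene that fell was the lipid transporter Mfsd2a, from 460 ± 75.2 to 275 ± 31.1 CPM. Of 16 mural and fibroblast genes, 11 rose, with the collagen gene Col3a1 at 37.5 ± 10.5 and 76.7 ± 29.0 CPM, Col1a1 at a log2 fold change of 1.22, Dcn at 1.14 and Col1a2 at 0.87.

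Of 21 astrocyte genes, 1 was higher in edgeR (3 in limma voom), the transporter Slco1c1 (0.59, SE 0.21, edgeR adjusted p = 0.0481, lost at 0.0734 to 0.150 without Control 2, 3, 4, 5 or 7 or Chd7iKO 2, 4 or 5). Among 23 neuronal genes, Nrgn rose (1.57) and 4 fell, of which Dcx, a marker of young neurons that precursors also express (-0.50), Snap25 (-0.29) and Map2 (-0.20) are examples. Of 9 ependymal genes, Foxj1 alone rose in edgeR (2 in limma voom; 0.39, adjusted p = 0.0300, lost at 0.0529 to 0.0819 without Control 2, 4 or 5 or Chd7iKO 2, 3 or 5), and 0 of 3 red blood cell genes passed in edgeR, with 0 at an unadjusted p under 0.05 and 0 in DESeq2 and limma voom. Immediate early genes, which respond to tissue dissociation, were higher for 9 of 23 and lower for 0, with Egr2 rising from 14.5 ± 4.24 to 31.8 ± 6.12 CPM and Ier5 (0.58), Ier3 (0.82) and Ier2 (0.58) rising too. The groups overlapped in the mean level of this list. Control 1 stood at 5.88 log2 CPM, within the range of the Chd7iKO libraries (5.51 to 6.07), and the other controls at 4.94 to 5.42.

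Camera called the microglial (adjusted p = 1.12e-06), endothelial (5.53e-04), mural (1.78e-04) and immediate early lists (1.27e-04) higher. None held, at adjusted p = 0.482 with an estimated correlation for microglia, 0.543 for endothelium, 0.533 for mural cells and 0.482 for immediate early genes. The astrocyte (0.710), neuronal (0.920), ependymal (0.875) and red blood cell lists (0.376) were not called by camera, although the astrocyte list was called higher without Control 1 (0.0363), which had the highest astrocyte mean; the neuronal median (0.11) and mean (0.20) were above 0 while its camera direction was downward, and the ependymal median (-0.18) and mean (-0.14) were below 0 while its camera direction was upward. Adjusted over the list alone, 19 microglial genes were higher, 16 endothelial genes higher and 1 lower, 12 mural genes higher, 9 immediate early genes higher, 1 neuronal gene higher and 4 lower, and 0 astrocyte, ependymal or red blood cell genes. Chd7iKO 4 and 5 had the highest mural means (4.82 and 4.96 log2 CPM, against 3.64 to 4.40 in the other Chd7iKO libraries and 2.54 to 4.11 in controls). Without Chd7iKO 4 and 5, 2 microglial, 0 endothelial, 1 mural and 3 immediate early genes were higher; without Controls 3 and 6 these counts were 20, 12, 12 and 9. The neuronal median was -0.19 without Chd7iKO 4 and 5, with 1 gene higher and 1 lower (camera adjusted p = 0.0855).

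**Figure D3:**
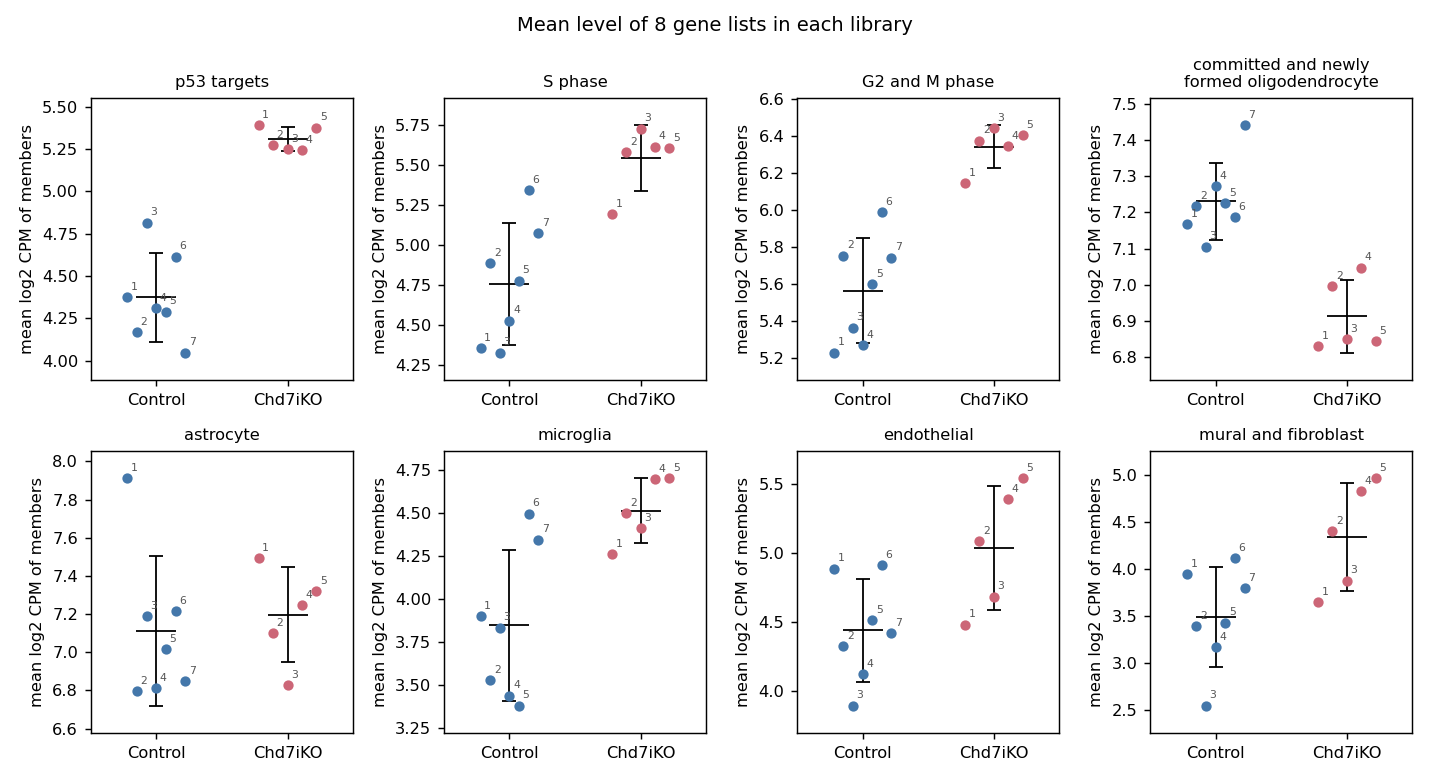
Mean log2 CPM of the measured members of 8 gene lists in each library (vertical axes), for the 7 Control and 5 Chd7iKO libraries; points are libraries with their number, horizontal marks are means and bars are SD. The p53 target means of Controls 3 and 6 (4.82 and 4.61) lie between the other controls and the Chd7iKO libraries, and the mural means of Chd7iKO 4 and 5 (4.82 and 4.96) are the highest.

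Housekeeping and chromatin lists moved little. Of 24 cholesterol synthesis genes, the sterol carrier Stard4 alone rose in edgeR (2 in limma voom; log2 fold change 0.29, SE 0.10, edgeR adjusted p = 0.0453, lost at 0.0546 to 0.101 without Control 3, 4, 6 or 7 or Chd7iKO 1, 2, 3 or 5), and 0 of the 10 CHD remodeller genes passed the threshold in edgeR, with 0 at an unadjusted p under 0.05, 0 in DESeq2 and 1 lower in limma voom; without Controls 3 and 6, 2 CHD genes were lower. Of 25 BAF complex genes, the subunits of a second chromatin remodeller, Bcl7a (-0.21), Smarca2 (-0.29) and Smarcd1 (-0.26) fell and 0 rose in edgeR (2 rose in limma voom, and 1 with scaling to library totals). Without Chd7iKO 4 and 5 these calls were lost (edgeR adjusted p = 0.106, 0.131 and 0.134), and 1 BAF gene was lower. Of 43 ribosomal protein genes, Rps19 alone rose in edgeR (0.26, SE 0.072, adjusted p = 0.0163), 3 rose in DESeq2 and 17 in limma voom, with a median log2 fold change of 0.092 over the list. Mitochondrially encoded transcripts were not analysed here, since 0 of the 15 listed names matched.

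Camera called ribosomal proteins higher (adjusted p = 0.00794), a call lost at adjusted p = 0.811 with an estimated correlation, and lost by camera itself without Chd7iKO 4 (0.0723) or Control 1 (0.0706). It did not call cholesterol synthesis (0.920), CHD remodellers (0.920) or the BAF complex (0.391). Adjusted over the list alone, 3 BAF genes were lower, and 0 genes of the cholesterol, CHD and ribosomal lists passed. With Controls 3 and 6 left out, 8 ribosomal protein genes were higher, and without Chd7iKO 4 and 5, 0 were.

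Genes with Chd7 bound nearby, from the authors' deposited lists, were compared with all tested genes to ask whether bound genes changed more often. Of 5555 bound genes in the table (92.3% of 6018 listed), 899 were lower, or 16.2% against 12.2% outside the list, and 725 were higher, or 13.1% against 17.5%. The lysosomal sulfatase Arsb fell from 613 ± 31.6 to 365 ± 19.4 CPM (SD, n = 7 and 5), the semaphorin Sema3d fell as given above, and the cadherin Cdh4 (log2 fold change 0.77) and the metalloprotease Adam19 (0.73) rose. Genes bound by both Chd7 and Chd8 (4905 in the table) showed the same directions, with 796 lower and 615 higher.

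The odds ratio for Chd7-bound genes was 1.39 among lower genes (95% interval 1.26 to 1.53, two-sided Fisher's exact test, p = 3.24e-11, p = 6.49e-11 after Benjamini-Hochberg adjustment over 6 tests) and 0.706 among higher genes (0.641 to 0.778, p = 7.26e-13, adjusted 2.18e-12). For genes bound by Chd7 and Chd8 it was 1.36 (adjusted p = 1.48e-09) and 0.677 (adjusted p = 4.49e-14). The median bound gene was more highly expressed, at 47.3 CPM against 22.2 CPM outside the list. Within 10 bins of mean expression the excess among lower genes was no longer past the threshold, at a Mantel-Haenszel odds ratio (chi-square test, two-sided) of 1.08 (0.977 to 1.20, p = 0.138) and 1.04 (0.934 to 1.15, p = 0.530). By the same chi-square test the deficit among higher genes stayed past the threshold, at 0.840 (0.760 to 0.929, p = 7.33e-04) and 0.816 (0.735 to 0.907, p = 1.73e-04). Without Chd7iKO 4 and 5, with fewer samples, the unmatched deficit was weaker. It was 0.841 (0.728 to 0.969, Fisher's exact test, p = 0.0154) and 0.818 (0.704 to 0.947, Fisher's exact test, p = 0.00687). The deficit at matched expression is given for all libraries only. All of these overlap tests take genes as independent, although genes can move together, and no test over the libraries was run. Their p-values and intervals can therefore overstate what 12 libraries show.

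Among autism risk genes, 169 of 201 listed were in the table, of which 21 were lower and 19 higher. The endosomal adaptor Tbc1d23 (log2 fold change -0.34), Serinc5 (-0.55) and the cell adhesion molecule L1cam (-0.56) were among those that fell. Neither direction differed from the other genes by Fisher's exact test, with odds ratios of 0.887 (95% interval 0.532 to 1.41, p = 0.736) for lower and 0.674 (0.394 to 1.09, p = 0.111) for higher genes. The latter passed without Control 1 (exact p = 0.0320) or Chd7iKO 1 (0.0373). The authors' deposited list of regulated Chd7-bound genes held 699 upregulated and 651 downregulated names, of which 578 and 587 were called in the same direction. Its limits differ from those used here. In the authors' own comparison its names reached a fold of 1.20 or more, with unadjusted p up to 0.0498 and adjusted p up to 0.140. Of the names, 650 and 605 are in the list of Chd7-bound genes used above. The regulated list was chosen on these libraries and is not independent evidence.

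**Figure D4:**
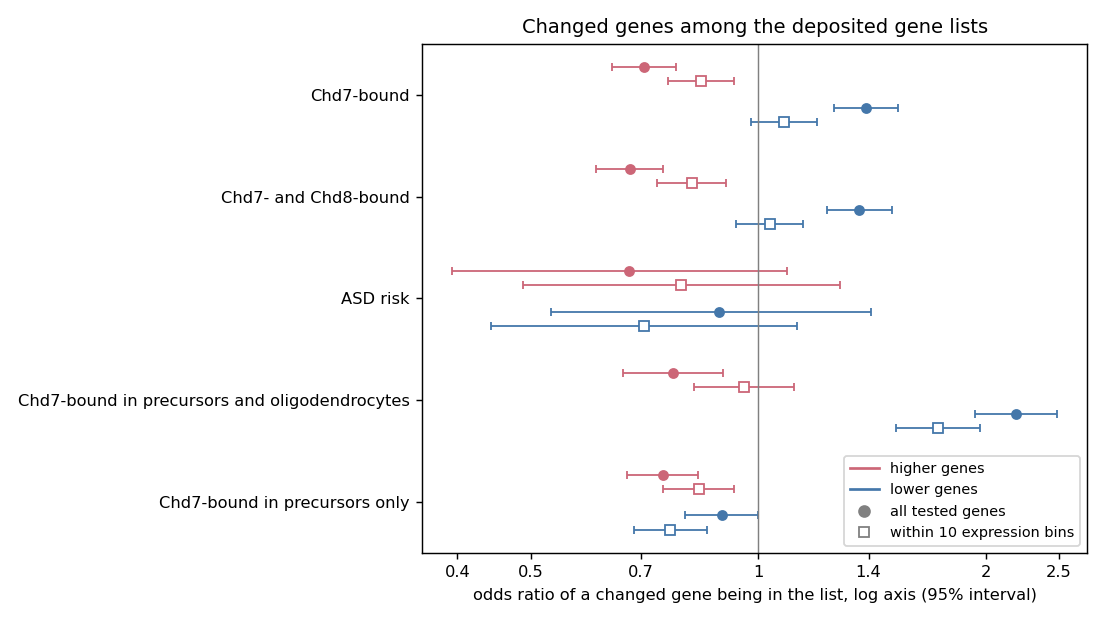
Odds ratio with its 95% interval (horizontal axis, log scale) for the overlap of higher (red) and lower (blue) genes with 5 deposited gene lists, over all tested genes (circles) and within 10 bins of mean expression (squares); the lower pair of lists was chosen after the data were seen. For Chd7-bound genes the ratio among lower genes is 1.39 over all genes and 1.08 within expression bins.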

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

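The tests on Controls 3 and 6, the test of sex make-up through the Y-linked covariate, the test of a lower share of lineage cells and the covariate of 3 mean scores were chosen only after the results were seen.

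The count of changed genes was weighed against chance. In 1 of 100 drawn splits of the 12 libraries into 7 and 5, the real one, at least 4167 genes were called. The highest other split gave 3382. Not all possible splits were drawn, so that this share could not fall below 1 in 100. Splits that mix the groups also put the group difference into the spread within each side, which can lower their calls. The real count was the highest of those drawn, but for these reasons the test cannot exclude chance for it. The split with 3382 calls set Controls 1 to 5 against Controls 6 and 7 with all 5 Chd7iKO libraries, so that the difference of the Chd7iKO libraries adds to its calls. A split with Controls 4 and 5 beside the Chd7iKO libraries instead called 0 genes. The number thus depends on which controls stand with them, which points to structure among the controls. For the number of called gene lists, 14 of 100 splits gave as many as the real 13, with 16 as the highest other, so that chance cannot be excluded for that number. The sex make-up of the libraries is argued against as the cause of the changed genes, since 96.6% of them (4025) kept their call and direction with the Y-linked level as a covariate, while an effect of Cre itself was not tested and stays open beside Chd7 deletion.

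The rise of S phase and mitosis genes came with a rise of vascular and microglial markers. The endothelial, mural and microglial score rose by 0.58 more than the astrocyte and neuronal score (two-sided exact permutation test, p = 0.00884). Without Chd7iKO 4 and 5, with fewer samples, the gap was 0.49 (two-sided exact permutation test, p = 0.0583). The gap cannot decide on a lower share of oligodendrocyte lineage cells. The neuronal list holds Dcx, which precursors also express and which fell, so that the reference score need not rise when that share falls. RNA of endothelial, mural or microglial cells cannot be told apart. The median log2 fold change of the 58 genes was 0.78 (median SE 0.14) without a covariate and 0.66 (SE 0.17) with the planned marker score, where 40 still passed, but that score holds astrocyte and neuronal genes and no mural genes. With the mean of the endothelial, mural and microglial scores it was 0.51 (SE 0.17) and 14 passed, the fold being smaller at a similar SE; this mean and the group were correlated at 0.69. A lower share of lineage cells, cycling microglia or vascular cells, and a change in proliferation of precursors after Chd7 deletion all remain as hypotheses that could not be separated by these values.

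Controls 3 and 6 lay between the groups in Esr1, at 52.0% and 28.2% of the way from the mean of the other 5 controls to the Chd7iKO mean, and in the risen p53 targets, where the lower of their median positions was 21.4% (Control 6) and the other was 38.4% (Control 3), against -7.68 to 4.06% in the other 5 controls. A hypothesis is that cells of Cre-carrying animals entered these libraries and that reads of an inducible Cre with an estrogen receptor part were counted to Esr1. For Control 6 this remains possible, since the lower of its median positions over strongly changed genes was 34.7%, against 20.4% and 25.3% at most in the other 5 controls for higher and lower genes. This position also moves with markers of other cell types: Control 6 stood at 99.8% for risen microglial and 58.5% for cell cycle genes, and Control 7, at 79.3% for microglial genes with 0.847 CPM of Esr1, at 18.7% and 23.5% for the strongly changed higher and lower genes. For Control 3 it cannot be told apart. Its position was 3.00% for the higher genes, within the range of the other 5 controls (-7.18 to 20.4%), and 26.9% for the lower genes, above theirs (-11.4 to 25.3%), but it had the lowest endothelial and mural means of all controls. On higher genes that keep their call with the mean of the 3 scores as a covariate, Control 3 stood at 18.7% and Control 6 at 29.6%, against -6.05 to 11.3% in the other 5 controls. Sex make-up is argued against, because the highest Esr1 level of the other 5 controls was 2.83% of the lower of the 2 libraries. RNA of endothelial, mural or microglial cells is argued against for both, since the controls nearest to them in these 3 marker scores had at most 1.55% of the Esr1 level of Control 3 and 1.90% of that of Control 6, at 88.8% or more of their marker levels, and stood at -7.68 to 4.06% in the p53 targets. Reads were not examined, so that the origin of the Esr1 counts was not tested directly.

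Single libraries stood far from the rest of their group in 12 of 238 groups tested (5.04%), and chance alone marks about 1 in 20. Chd7iKO 1 had 91.6 CPM of Trp53, above 89.5 to 89.98 in the other Chd7iKO libraries. Its Apaf1 level was 51.5 CPM against 61.1 to 64.9, its Smarca2 level 179 CPM against 145 to 154, and its Smarcd1 level 189 CPM against 155 to 161. The S phase mean of Chd7iKO 1 was 5.19 log2 CPM, below 5.58 to 5.73. Chd7iKO 5 had 64.3 CPM of Neu4 against 70.7 to 72.9, and 331 CPM of Arsb against 366 to 378. Control 3 had 11.3 CPM of Bbc3, above 6.09 to 7.58 in the other controls, and 9.05 CPM of Dcn, below 18.2 to 27.5. Control 7 had 2805 CPM of Mbp, above 1846 to 2153. Control 6 had a mean of 6.57 log2 CPM for the lineage transcription factors, below 6.69 to 6.77, and Control 1 one of 7.91 for astrocyte genes, above 6.79 to 7.21.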

How the results depend on the processing

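The fits without Controls 3 and 6, without Chd7iKO 4 and 5 and with the Y-linked covariate, and the matching through synonyms, were chosen only after the results were seen. Other scalings gave 4153 (DESeq2 size factors), 4099 (upper quartile) and 4036 changed genes (library totals), DESeq2 gave 4739, and both other filters removed 0 genes and so test nothing. The count moved to 6462 in limma voom, to 1770 with the score of other cell types as a covariate (1701 of them shared), to 1747 without Chd7iKO 4 and 5 (fewer samples), and, by stricter limits, to 2056 at an adjusted p under 0.01 and 1428 at a 1.5-fold change or more (1164 higher, 264 lower). Leaving out 1 library gave 2690 (without Chd7iKO 5) to 4612 (without Control 6). For the rest the cause was not tested. The pseudocount, value filter and array weights planned for values other than counts were not run.

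The replicate numbers do not pair the samples throughout: same-numbered libraries correlated at 0.376, -0.12, 0.084, -0.127 and -0.177, and 1 of 5 correlated best with its own number. That was number 1. Control 1 and Chd7iKO 1 also stood apart on the second principal component (14.8% of the variance), at 25.1 and 31.6 against at most 4.39 elsewhere. They had the highest astrocyte means (7.91 and 7.49 log2 CPM). What these libraries share is not given in the sources used here. With the number as a block, 4780 genes were called, 3721 of them shared; the myelin list lost its call (0.122), and Pdgfra (0.0587) and Slco1c1 (0.0544) lost theirs.

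The lists called by camera fell from 13 to 0 with an estimated correlation, where 3 lists had an unadjusted p under 0.05, and fry called 11. Direction turned for uncalled lists: the neuronal list under fry (0.919), the block (0.785) and the Y-linked covariate (0.940), with 0.366 to 0.984 over the libraries left out; cholesterol synthesis (0.756) and CHD remodellers (0.478) without Controls 3 and 6, with 0.659 to 0.978 and 0.637 to 0.965; ependymal genes without Chd7iKO 4 and 5 (0.527), with 0.463 to 0.988. The astrocyte list ranged from 0.0363 (without Control 1) to 0.937, so that it was called once.

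Chd7 turned to -0.062 in limma voom and -0.053 without Controls 3 and 6, and ranged from -0.029 to 0.090 over the libraries left out; none of these passed the threshold. Chd8 turned to 0.0034 (upper quartile), 0.020 (library totals), 0.044 (other cell types) and 0.064 (without Chd7iKO 4 and 5), with -0.084 to 0.035 over the libraries left out, and Mbp to 0.013 under the block, with -0.13 to 0.044. Of 2744 pairs of a setting and 1 of the 98 genes that the naming rule selects, 2576 kept direction and side of the threshold, 148 lost the call, 4 gained it and 16 turned direction; 53 genes kept both in every setting run. With the score of other cell types as a covariate, 70 of the 98 genes kept both, 27 lost the call and 1 turned direction. Further calls lost without 1 library were Smarcd1 without Chd7iKO 2 (adjusted p = 0.0509), Esam without Chd7iKO 4 (0.0535) or 5 (0.0632), and Rps19 (0.0507), Cldn5 (0.0545), Sox17 (0.0655) and Col1a2 (0.0512) without Chd7iKO 5.

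The excess of lower genes among Chd7-bound genes was 1.08 (p = 0.138) and among genes bound by Chd7 and Chd8 1.04 (p = 0.530) at matched expression (Mantel-Haenszel chi-square test). The ratio for autism risk genes was 0.639 (Fisher's exact test, p = 0.0375) among higher genes at an unadjusted p under 0.05. Among lower genes it turned to 1.14 at an adjusted p under 0.01 and 1.01 with synonyms. Over the libraries left out it was 0.591 to 0.805 for higher and 0.798 to 1.19 for lower genes. At this depth and spread, 30% of the smallest simulated changes were found, so that small changes can be missed. The simulation planted 50 genes at each fold, against 4167 genes called here. Its adjusted threshold was therefore stricter, and the 30% does not carry over directly.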

Other observations

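All tests in this part were chosen only after the results were seen.

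Interferon-stimulated genes were higher in Chd7iKO cells. After Usp18 appeared among the largest rises, a list of such genes was drawn up, and 36 of 38 measured members rose and 0 fell, with a median log2 fold change of 1.21. The antiviral effector Ifit1 rose from 0.913 ± 0.507 CPM (SD, n = 7) to 4.57 ± 0.906 CPM (n = 5), the regulator Irf7 from 1.65 ± 0.971 to 7.29 ± 1.47 CPM, and the ubiquitin-like Isg15 from 0.782 ± 0.388 to 3.07 ± 1.06 CPM. Camera gave an adjusted p of 7.91e-23 over 22 lists, lost at adjusted p = 0.198 with an estimated correlation. Without Controls 3 and 6, 36 were higher and the adjusted p = 0.0369 with an estimated correlation. Leaving out these 2 controls, which lay toward the Chd7iKO libraries in the largest rises, favours such a call, so that it is no independent support. Without Chd7iKO 4 and 5, 30 were higher. Microglial markers were higher in the same libraries, and several of these genes are expressed in many cell types.

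Clustered protocadherins, neuronal and glial adhesion genes that lie in tandem arrays, were lower. Among 153 families of genes with a shared name stem, 27 were called by camera and 0 with an estimated correlation. In the Pcdhb family 17 of 21 genes fell (median log2 fold change -0.47), in Pcdha 9 of 12 (-0.72) and in Pcdhga 9 of 12 (-0.30), each at adjusted p = 0.558 with an estimated correlation. All 3 medians stayed below 0 under the other scalings run. Without Chd7iKO 4 and 5 the counts were 10, 2 and 3, and without Controls 3 and 6 they were 16, 10 and 9. Members of these arrays share sequence, so that counts can pass between them. In the same libraries microglial, endothelial and mural markers were higher, with median log2 fold changes of 0.61, 0.66 and 0.89. Nucleoporin genes were higher for 11 of 19 and collagen genes for 19 of 40, with 4 collagen genes lower. Without Chd7iKO 4 and 5, which had the highest mural means, 9 nucleoporin genes were higher, and 5 collagen genes were higher and 1 lower.

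Genes bound by Chd7 in both precursors and oligodendrocytes were lower more often than other genes. Of 1699 such genes 403 fell (23.7% against 12.4% outside), an odds ratio of 2.19 (95% interval 1.93 to 2.49, two-sided Fisher's exact test, p = 1.98e-32) and of 1.73 (1.52 to 1.97) at matched expression. The overlap tests here too take genes as independent, so that p-values and intervals can overstate what the libraries show. Genes bound in precursors only had 0.896 (0.801 to 1.00) and 0.765 (0.684 to 0.855), and the difference between these lists was not tested directly. Without Controls 3 and 6 the matched ratio was 1.94 for the first list and 0.768 for the second. For genes bound in oligodendrocytes only, the matched ratio was 1.04 among lower genes, for Chd7 without Chd8 1.24 (0.995 to 1.55), and for Chd8 without Chd7 0.869. Without Controls 3 and 6 the ratio for Chd7 without Chd8 was 1.39 (1.13 to 1.72, unadjusted p = 0.00238), past the threshold. For autism risk genes bound by Chd8 the odds ratio among higher genes was 0.435 (Fisher's exact test, p = 0.0196 after adjustment over 20 tests), and for those bound by Chd7 0.399 (adjusted p = 0.0550); neither passed at matched expression (adjusted p = 0.225 and 0.258).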
